A study of Mus musculus with 16 samples.

How the data were processed

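Expression was measured in 16 B16-BL6 melanomas grown in 8-week-old male C57BL/6J mice, 4 in each of 4 groups: control, ALA (50 mg per kg, given locally), X-ray, and ALA plus X-ray with ALA before each fractionated irradiation. Each tumour preparation was hybridised to a 1-colour Agilent whole-genome mouse array, on 4 slides that carried 1 array of each group. Slide and replicate number agreed on all 16 arrays, each slide had a scan number of its own, and position on the slide followed the group, so an effect of position and an effect of group cannot be told apart.

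Per the file headers, the scanner files hold spot values as intensity on a linear scale: the processed signal (background-subtracted and detrended within the array by Agilent Feature Extraction 10.7.3.1), the mean signal and the local background median, with quality flags as other values. The authors' processing notes name version 9.5.3.1 instead. The deposited value table holds intensity on a linear scale that was quantile normalised between the arrays: each of its columns had a median of 31.881 and a mean of 1723.6, and its log2 values correlated with the processed signal at 0.9925 to 1. The processed signal was used here and the authors' table as an alternative.

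Each array held 43379 spots other than 1639 control spots. The log2 processed signal was scaled by subtracting the array's 75th percentile over the non-control spots, and spots of a probe that were not marked as non-uniform or population outliers were averaged; 39 probes with no such spot on an array were left out. Of 41174 probes, 26974 were named by accession, 2833 by symbol and 332 by an older symbol, and 11035 kept the name in the file, which gave 30022 distinct names; positions are those of the array annotation (mm9). Probes well above background on at least 4 of the 16 arrays were kept, and the probe with the highest mean stood for its gene, which left 15398 genes. Cd8a fell below this filter.

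The 75th percentile of the processed signal was 213 to 408 in control, 217 to 331 in ALA, 224 to 478 in X-ray and 366 to 521 in ALA plus X-ray arrays; 44.3% to 53.6% of spots were well above background and 0 were saturated. Within a group the log2 values of array pairs correlated at 0.9667 to 0.9838 (control), 0.9702 to 0.9833 (ALA), 0.9451 to 0.9807 (X-ray) and 0.9265 to 0.9816 (ALA plus X-ray), and the median standard deviation of a gene was 0.194, 0.215, 0.245 and 0.334.

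Linear models (limma 3.58.1 in R 4.3.3, with the data.table package, version 1.17.8) were fitted to the 4 group means with moderated variances (12 residual and 2.3 prior degrees of freedom). The 6 comparisons were X-ray against control, ALA against control, ALA plus X-ray against X-ray, ALA plus X-ray against control, ALA plus X-ray against ALA, and the interaction of ALA and X-ray. P-values were adjusted by the Benjamini-Hochberg method within each comparison at a threshold of 0.05. Gene lists were 14 pathway lists (p53 targets, mitosis and G2/M, G1/S and DNA replication, DNA repair, apoptosis regulators, heme synthesis and handling, antioxidant response, interferon response, antigen presentation, inflammatory cytokines and chemokines, hypoxia and glycolysis, pigmentation, unfolded protein and amino acid stress response, mitochondrial respiratory chain) and 13 marker sets of cell types. They were tested with camera at a preset inter-gene correlation of 0.01; 26 of the 27 were tested, since the mast cell set had too few genes past the filter. No camera call in any comparison had an adjusted p under 0.05 with an estimated correlation. Fry, which tests whether the genes of a list move on balance 1 way without comparing them with other genes, was run as an alternative.

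Genes are named by a rule set before the data were examined, as were the comparisons, tests, lists and all alternatives but 3. For the first 4 comparisons the rule names the 8 genes with the largest rise and the 8 with the largest fall among genes that passed and whose array values did not overlap between groups, leaving out clone and prediction names, or the 3 of smallest p in a direction where fewer than 3 passed. It adds the 4 members of smallest p in the direction of each shifted list and, whatever their values, Cdkn1a, Mdm2, Ccng1, Mki67, Ccnb1, Alas1, Fech, Hmox1, Abcg2, Tyr, Ptprc, Cd3e, Cd8a, Gzmb, Adgre1, Ifit1, Il1b and Pecam1. For the interaction it names up to 5 genes per direction without the criterion on overlap. A few genes that the rule names are not reported here.

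Alternatives were a normexp background (offset 50), quantile or median scaling, the authors' table, no filter or a filter on all 16 arrays, all probes, a fit on only the arrays compared, slide as a block, trend and robust moderation, array weights, a 2-fold minimum, each array left out, an estimated correlation and fry. The 3 alternatives chosen after seeing the data were the 75th percentile over spots well above background on all arrays, the skeletal muscle marker level as a covariate, and the first slide left out. Whether the replicate numbers pair the samples was checked on residuals: 24 same-numbered pairs of different groups correlated at -0.46 to 0.54 with a mean of 0.08, and 9 lay above 0.1, so the numbers were not taken as pairs and slide was kept as an alternative block.

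The procedure was tested on simulated independent genes, 200 of 15398 changed. In X-ray against control it recovered 22.4%, 65.7% and 87.9% of genes changed 1.5, 2 and 4-fold and called 4 unchanged genes. In ALA plus X-ray against X-ray these were 20.9%, 59.7%, 90.9% and 4. A list shifted by 0.5 was recovered in both, with 0 and 1 other lists called. Correlated lists were not simulated. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15. Control spots and the X-ray dose, not in the labels, were not analysed.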

Results

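Irradiation of B16-BL6 mouse melanomas raised the p53 target gene Cdkn1a and lowered genes of DNA replication and repair. Against control, tumours given 5-aminolevulinic acid (ALA) before irradiation shared these changes and had higher interferon, antigen presentation and macrophage genes. Against X-ray alone no interferon response gene passed, and chance is not excluded for the gene count. ALA, a heme precursor, yields the photosensitiser protoporphyrin IX in cells. The series asks what ALA adds to X-ray. Its 16 arrays, 4 per group, measured separate tumour preparations, so limma p-values measure the spread between them. Camera p-values at the preset correlation compare genes with other genes instead. Of 15398 genes tested, 519 changed in X-ray against control, 0 in ALA against control, 318 in ALA plus X-ray against X-ray and 3828 in ALA plus X-ray against control, at an adjusted p under 0.05.

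**Figure D1:**
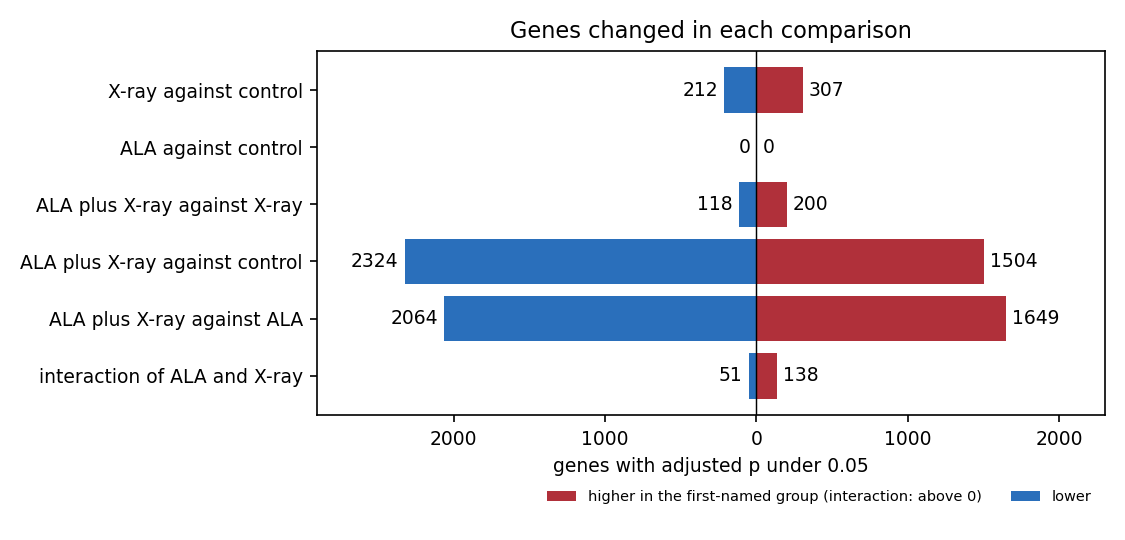
Number of genes with an adjusted p under 0.05, higher and lower, in each of the 6 comparisons (limma, 15398 genes, 4 arrays per group).

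X-ray alone changed 519 genes, 307 higher and 212 lower. Cdkn1a, which encodes the cell cycle inhibitor p21, was among the rises, and Pcna and Mcm4, which serve at the replication fork, were among the falls. In limma, 152 of the 519 genes changed at least 2-fold, 3374 genes had an unadjusted p under 0.05, and 2821 genes had 4 and 4 array values that did not overlap, where chance gives 2.86%. Scaled to the median of each array instead, 28 genes passed, 27 higher and 1 lower. That scaling moved the median of all genes to -0.06 in X-ray against control, -0.12 in ALA against control and -0.14 in ALA plus X-ray against control. Each slide carried 1 array of every group, and a fit with slide as a block called 489 genes. With the skeletal muscle level of each array as a covariate 812 passed, and with no filter on dim probes 3. Without 1 array the count was 1 (X-ray replicate 1), 11 (X-ray 2), 836 (X-ray 3), 5 (X-ray 4), 158 (control 1), 2 (control 2), 242 (control 3) or 5 (control 4), and without the first slide it was 4.

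The adhesion gene Igsf21 rose by a log2 fold change of 3.23 (SE 0.44, 9.38-fold, adjusted p = 0.0143, probe on chromosome 4, 139582816 to 139582875 in mm9). The zinc finger gene Zfp536 rose by 3.20 (adjusted p = 0.0243), Wfdc3, of the whey acidic protein family, by 2.89 (0.0287), the transmembrane protein gene Tmem82 by 2.55 (SE 0.27, adjusted p = 0.00289) and the phosphodiesterase gene Pde10a by 2.39 (0.0208). Where a gene was well above background on none of a group's arrays, its fold is a lower bound, taken against the dimmest signal called well above background on that group's arrays. On that basis the olfactory receptor gene Olfr533 was at least 3.08-fold higher (adjusted p = 0.0167), the p21-activated kinase gene Pak3 at least 2.54-fold (0.0208) and the osteocalcin gene Bglap at least 4.97-fold (0.0412). The vitronectin gene Vtn fell with a log2 fold change of -2.28 (SE 0.49, adjusted p = 0.0295), the matrix gene Aspn of -2.01 (0.0465), the histidine ammonia-lyase gene Hal of -1.97 (0.0281) and the organic anion transporter gene Slco2b1 of -1.86 (0.0446). C1qtnf9, an adiponectin relative, was at least 2.23-fold lower (adjusted p = 0.0222), Nrarp, a Notch target, at least 1.75-fold (0.0391) and Stra6l at least 1.09-fold (0.0402). The urate oxidase gene Uox fell too (adjusted p = 0.0282), but no fold is given because it was well above background on 0 X-ray and 2 control arrays. The sizes depended on the processing and were smallest with the normexp background: over the alternatives Igsf21 ranged from 1.56 to 3.44, Zfp536 from 0.83 to 3.78, Wfdc3 from 1.65 to 3.36, Tmem82 from 1.07 to 2.83 and Pde10a from 0.71 to 2.63. Vtn ranged from -2.76 to -0.91, Aspn from -2.28 to -0.79, Hal from -2.24 to -0.63 and Slco2b1 from -2.26 to -0.73. With the slide block, Bglap (adjusted p = 0.0549), Aspn (0.063), Slco2b1 (0.0555) and Nrarp (0.0588) no longer passed. Of the 31 genes named for this comparison that passed, Tmem82 passed without every array, and each of the others missed the threshold without at least 1. Lost were 21 without control replicate 1, 29 without control 2, 16 without control 3, 28 without control 4, 30 without X-ray 1, 28 without X-ray 2, 3 without X-ray 3 and 28 without X-ray 4, with adjusted p up to 0.131.

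The p53 target genes were higher after X-ray, and the replication genes were all lower. Cdkn1a rose by 1.52 on the log2 scale (SE 0.21, adjusted p = 0.0143, probe on chromosome 17, 29237377 to 29237436 in mm9), and Polk, a translesion polymerase gene, rose by 0.97, the apoptosome gene Apaf1 by 0.59 and the adenylate kinase gene Ak1 by 1.18 (adjusted p 0.0167, 0.0348 and 0.0418). Of 31 p53 targets, 4 rose and 0 fell (8 and 1 adjusted over the list alone). Their median log2 fold change was 0.38 (camera, adjusted p = 1.25e-05, adjusted p = 0.95 with an estimated correlation). All 31 G1/S and DNA replication genes were below 0, 8 fell (21 adjusted over the list alone) and their median was -0.72 (adjusted p = 1.16e-13, adjusted p = 0.95 with an estimated correlation). Pcna, the sliding clamp gene, fell with a log2 fold change of -0.70 (SE 0.15, adjusted p = 0.0294, probe on chromosome 2, 132075420 to 132075557 in mm9), the uracil glycosylase gene Ung of -0.73 and the helicase gene Mcm4 of -0.79 (adjusted p 0.0244 and 0.0319). Of 29 DNA repair genes, 4 fell (8 adjusted over the list alone), among them the mismatch repair gene Msh6 (-0.76), the checkpoint kinase gene Chek1 (-1.05) and the end-joining gene Xrcc4 (-0.69), with adjusted p of 0.0295 to 0.0306. Their median was -0.33 (adjusted p = 3.5e-06, adjusted p = 0.95 with an estimated correlation). All 30 mitosis and G2/M genes were below 0 with a median of -0.44 (adjusted p = 1.06e-06, adjusted p = 0.95 with an estimated correlation), and 1 fell, the mitotic kinase gene Aurkb, at -0.77 (adjusted p = 0.0364; 5 fell adjusted over the list alone). Mad2l1 (-0.65), Cdc20 (-0.65) and Cdk1 (-0.76) had adjusted p of 0.053 to 0.094. Each of these 4 medians kept its sign within every slide, and slide 3 had the smallest (p53 targets 0.28, replication -0.27, repair -0.08 and mitosis -0.01). With the slide block, Ak1 (adjusted p = 0.0505), Aurkb (0.0601) and Mcm4 (0.0518) missed the threshold.

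All 32 interferon response genes were above 0 after X-ray, hypoxia genes were mostly higher and macrophage markers mostly lower, but the interferon and macrophage calls were each lost without 1 tumour. The interferon list had a median of 0.78 (adjusted p = 1.18e-05, adjusted p = 0.95 with an estimated correlation), with 0 members passing in limma over all genes and 0 adjusted over the list alone. Ifit1, an antiviral effector gene, had a log2 fold change of 2.34 (adjusted p = 0.103), Mx2 1.78, Rsad2 1.10 and the RNA sensor gene Ddx58 0.94 (adjusted p 0.11 to 0.171). Without X-ray replicate 1 the median was 0.09 (adjusted p = 0.303). Within slides 1 to 4 it was 4.01, 0.71, -0.27 and -0.55. Of 24 hypoxia and glycolysis genes, 22 were above 0 and 2 rose (8 adjusted over the list alone): the stress gene Ndrg1 by 1.15 (adjusted p = 0.0289) and the oxidoreductase gene Ero1a by 1.74 (0.0368; 0.0583 with the slide block). P4ha1 (0.74) and Mxi1 (0.95) had adjusted p of 0.0526 and 0.0705. The hypoxia median was 0.49 (adjusted p = 1.1e-06, adjusted p = 0.95 with an estimated correlation). Of 15 macrophage and monocyte markers, 14 were below 0 and 0 passed by either adjustment. The median was -1.09 (adjusted p = 0.0156, adjusted p = 0.95 with an estimated correlation), and Ms4a7 (-1.83), Csf1r (-1.77), Adgre1 (-1.45) and Itgam (-1.43) had adjusted p of 0.116 to 0.259. The median lost its call with the muscle covariate (-0.93, adjusted p = 0.0655), in a fit on only the arrays compared (0.0547) and without control replicate 3 (-0.91, adjusted p = 0.0694), control 4 (-0.89, 0.0633), X-ray 3 (-0.83, 0.157) or X-ray 4 (-0.54, 0.314). Within slides 1 to 4 it was 1.21, -0.48, -1.81 and -3.05.

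The other lists did not shift after X-ray. Median log2 fold changes, also given with dim genes at their bound where that differs, were 0.10 for apoptosis regulators (adjusted p = 0.315), 0.13 for the antioxidant response (0.0845), 0.50 for antigen presentation (0.37 at bound, 0.148) and -0.29 for inflammatory cytokines and chemokines (-0.12 at bound, 0.986). They were -0.04 for pigmentation (0.986), -0.14 for the unfolded protein and amino acid stress response (0.512), 0.04 for the mitochondrial respiratory chain (0.371) and -0.04 for heme synthesis and handling (0.96). Among immune markers they were 0.47 for T and NK cells (0 at bound, adjusted p = 0.315), 0.46 for neutrophils (0.966), -0.01 for B and plasma cells (0 at bound, 0.977) and -0.06 for dendritic cells (0.515). Other cell markers had -0.43 for endothelial cells (0.0845), -0.47 for fibroblasts and matrix (-0.37 at bound, 0.752), -0.26 for pericytes and smooth muscle (0.561), -0.60 for skeletal muscle (0.512), -0.41 for adipocytes (-0.22 at bound, 0.489), -0.02 for keratinocytes (0.986) and 1.12 for erythroid cells (0.204). The mean or the test had the opposite sign to the median for the heme, inflammatory, pigmentation, dendritic and keratinocyte lists. Of the genes named whatever their value, Mdm2, which encodes the ubiquitin ligase of p53, had a log2 fold change of 0.50 (adjusted p = 0.134), the p53 target Ccng1 0.80 (0.143), the proliferation marker Mki67 -0.36 (0.556) and Ccnb1 -0.56 (0.218). The heme genes Alas1 (-0.25), Fech (0.08) and Hmox1 (0.79), the porphyrin exporter gene Abcg2 (-0.13) and the tyrosinase gene Tyr (-0.26) had adjusted p of 0.262 to 0.872. The pan-leukocyte gene Ptprc (-1.25), the T cell gene Cd3e (0.83), Il1b (-0.47) and the endothelial gene Pecam1 (-0.51) had adjusted p of 0.342 to 0.848. The cytotoxic granule gene Gzmb was well above background on 0 control and 1 X-ray array, so no fold is given (adjusted p = 0.713).

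ALA alone changed 0 genes, while macrophage markers were all lower and the 4 erythroid markers all higher than in control tumours. Hypoxia genes were mostly higher, and skeletal muscle markers were all lower. In limma 961 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.391. Array weights called 40 genes, a fit on only the arrays compared 2, and the slide block 0. Groups did not overlap for 877 genes, where chance gives 2.86%. Without ALA replicate 2, 1 gene passed. The rises of smallest p, none of which passed, were the platelet receptor gene Gp1bb (log2 fold change 1.35), the F-box gene Fbxw15 (1.80) and Lypd2 (1.36), each with an adjusted p of 0.482. The falls were the Fc receptor-like gene Fcrls (-1.90), Fgf14 (at least 1.2-fold lower) and the amino acid transporter gene Slc16a10 (no fold, well above background on 0 ALA and 2 control arrays), at the same adjusted p. Alas1, the rate-limiting heme synthesis gene, had a log2 fold change of -1.15 (SE 0.35) and Hmox1, the heme-degrading oxygenase gene, 1.16 (SE 0.39), each with an adjusted p of 0.755. Other genes named whatever their value were Cdkn1a (-0.53), Mdm2 (0.04), Ccng1 (-0.65), Mki67 (-0.04), Ccnb1 (-0.22), Fech (0.12), Abcg2 (-0.32), Tyr (-0.20), Ptprc (-1.56), Cd3e (0.65), Adgre1 (-2.64), Ifit1 (0.34), Il1b (0.28) and Pecam1 (-0.06), with adjusted p of 0.755 to 0.986. Gzmb was well above background on no array of either group (adjusted p = 0.924).

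All 15 macrophage and monocyte markers were below 0 in ALA tumours, with a median of -1.72 (adjusted p = 8.61e-15, adjusted p = 0.76 with an estimated correlation); 0 passed over all genes in limma and 10 fell adjusted over the list alone. Ms4a7 (-2.94), the complement genes C1qa (-2.97) and C1qc (-2.74) and the lysozyme gene Lyz2 (-1.72) had adjusted p of 0.482 to 0.755. The median kept its sign within slides 1 to 4, at -0.88, -1.01, -3.21 and -2.61. The 4 erythroid markers had a median of 2.29 (adjusted p = 0.000365, adjusted p = 0.773 with an estimated correlation; 2 rose adjusted over the list alone), with the globin genes Hbb-bt at 2.25 and Hba-a1 at 2.39, Alas2 at 2.32 and Slc4a1 at 1.96. Of 24 hypoxia genes, 23 were above 0, with a median of 0.33 (adjusted p = 4.07e-06, adjusted p = 0.909 with an estimated correlation), Ndrg1 at 0.80, Ero1a at 1.27, P4ha1 at 0.47 and Mxi1 at 0.64. In slide order the medians were 0.54, -0.48, 0.72 and 0.96. Antioxidant genes had a median of 0.16 (adjusted p = 0.00234, adjusted p = 0.909 with an estimated correlation), led by the glutathione synthesis genes Gclm (0.63) and Gclc (0.44) and the metallothionein genes Mt2 (0.39) and Mt1 (0.36). Per slide the list had medians of -0.01, -0.01, 0.26 and 0.29. Each of these lists had 0 members passing over all genes, and the hypoxia and antioxidant lists had 0 adjusted over the list alone; the antioxidant call was lost without control replicate 4 (0.12, adjusted p = 0.0557) and with the muscle covariate (0.10, 0.0779).

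Skeletal muscle, fibroblast and antigen presentation lists were lower in the ALA than in the control tumours, mainly on slides 3 and 4. All 15 skeletal muscle markers were below 0, with a median of -2.75 (-2.32 with dim genes at their bound, adjusted p = 3.72e-05, adjusted p = 0.909 with an estimated correlation). Ckm was at least 3.8-fold, Mb at least 2.25-fold, Pvalb at least 2.01-fold and Ttn at least 1.53-fold lower (adjusted p 0.804 to 0.818). Slides 1 to 4 gave medians of -0.08, 1.60, -7.90 and -4.53. Of 17 fibroblast and matrix markers, 14 were below 0 with a median of -0.74 (-0.69 at bound, adjusted p = 0.00629, adjusted p = 0.911 with an estimated correlation), among them Col6a1 (-0.69), Postn (-1.11), Col1a1 (-0.92) and Fap (no fold). Within slides the fibroblast median was 1.35, 0.13, -2.39 and -1.92. Antigen presentation had a median of -0.48 (-0.43 at bound, adjusted p = 0.0189, adjusted p = 0.911 with an estimated correlation), with the MHC class II genes H2-Ab1 (-1.64), H2-Eb1 (-1.57), H2-Aa (-1.5) and Cd74 (-1.27). By slide, in order, the median was 0.15, -0.08, -0.54 and -1.16. Endothelial markers had a median of -0.21 (adjusted p = 0.0312, adjusted p = 0.911 with an estimated correlation), with Kdr (-0.52), Plvap (-0.51), Emcn (-0.41) and Cdh5 (-0.44). The slide medians were -0.14, 0.05, -0.56 and -0.39. The p53 targets had a median of -0.17 (-0.09 at bound, adjusted p = 0.00561, adjusted p = 0.909 with an estimated correlation), with Ddit4l (-0.83) and Eda2r (no fold) beside Cdkn1a (-0.53) and Ccng1 (-0.65). Mitosis genes had a median of -0.10 (adjusted p = 0.0325, adjusted p = 0.916 with an estimated correlation), with Hmmr (-0.38), Aurkb (-0.29), Cdc20 (-0.31) and Aurka (-0.27). Replication genes had a median of -0.14 (adjusted p = 0.0118, adjusted p = 0.911 with an estimated correlation), with Tyms (-0.41), Pola1 (-0.31) and Pcna (-0.19). No member of these lists passed in limma, over all genes or adjusted over the list alone. Calls were lost without control replicate 2 (mitosis -0.07, adjusted p = 0.171), control 3 (antigen presentation -0.50, 0.0716; endothelial -0.18, 0.0543; fibroblast -0.61, 0.161; muscle -1.38, 0.0716) or control 4 (mitosis -0.10, 0.106; replication -0.12, 0.0557; antigen presentation -0.29, 0.165; endothelial -0.14, 0.143; fibroblast -0.53, 0.107). They were also lost without ALA 2 (mitosis -0.14, adjusted p = 0.0897), ALA 3 (endothelial -0.08, 0.152) or ALA 4 (mitosis -0.07, 0.129; replication -0.12, 0.0807; antigen presentation -0.42, 0.0807; endothelial -0.20, 0.0807; fibroblast -0.56, 0.0863). The muscle covariate ended the calls of p53 targets (-0.03, adjusted p = 0.256), antigen presentation (-0.15, 0.597), endothelial (-0.21, 0.157), fibroblast (0.02, 0.762) and muscle markers (-0.10, 0.72). The mitosis call was also lost with the normexp background (-0.09, adjusted p = 0.158), quantile normalization (-0.06, 0.0754), median scaling (-0.22, 0.0754) and the authors' table (-0.07, 0.0749). Endothelial and fibroblast calls were lost with the normexp background (-0.06, adjusted p = 0.191; -0.32, 0.0522) and the endothelial call with array weights (-0.21, 0.0868). Median scaling ended the antigen presentation call (-0.60, adjusted p = 0.0547), and a filter on all 16 arrays ended that call (-0.30, 0.0596) and those of endothelial (-0.21, 0.0529) and muscle markers (-1.68, 0.125). The other 15 lists did not shift (adjusted p 0.079 to 0.821), including heme synthesis and handling (-0.09, adjusted p = 0.655), interferon response (-0.04, 0.782) and pigmentation (-0.05, 0.821).

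ALA plus X-ray tumours expressed more macrophage genes than tumours given X-ray alone. The rises included Ctss, the cathepsin S gene of antigen-presenting cells, the complement gene C1qc and the macrophage receptor gene Adgre1, together with the adhesion gene Vcam1. Cdkn1a differed by -0.06 between the groups (adjusted p = 0.883). In limma 318 genes changed, 200 higher and 118 lower, 199 of them at least 2-fold. Of all genes 3565 had an unadjusted p under 0.05, and 985 had groups that did not overlap, where chance gives 2.86%. The slide block left 322 genes and the median of each array 243, 206 higher and 37 lower. Without 1 array the count was 3134 (ALA plus X-ray replicate 1), 4 (ALA plus X-ray 2), 3 (ALA plus X-ray 3), 7 (ALA plus X-ray 4), 1093 (X-ray 1), 9 (X-ray 2), 4 (X-ray 3) or 5 (X-ray 4). Without the first slide it was 2982, and a fit on only the arrays compared called 1. The muscle covariate left 76 genes, 5 of the 24 named ones that had passed and 0 of the macrophage markers, with Adgre1 at 2.73 (SE 0.67, adjusted p = 0.077). With no filter on dim probes 11 passed, 3 of the 24 among them.

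The largest rises over X-ray alone were the Wnt-binding gene Sfrp2 with a log2 fold change of 5.00 (SE 1.20, adjusted p = 0.0473), the retinol carrier gene Rbp4 of 4.73 (0.0374) and Vcam1 of 3.95 (0.0374). Sfrp2, Rbp4, Vcam1 and Nxpe5 were each well above background on 1 X-ray array, and their size depended on the processing: over the alternatives they ranged from 2.29 to 6.51, 2.04 to 5.60, 1.80 to 5.00 and 1.41 to 4.30. Ctss rose by 3.50 (SE 0.67, adjusted p = 0.0328), Wfdc17 by 3.50 (0.0374) and Nxpe5 by 3.37 (0.0374). Uox was at least 2.66-fold higher (adjusted p = 0.00896). The teneurin gene Tenm4 had the largest fall that was not a bound, -2.66 (SE 0.34, adjusted p = 0.00896, probe on chromosome 7, 104055032 to 104055091 in mm9), and Olfr533 was at least 3.91-fold lower (adjusted p = 0.00896; chromosome 7, 147652712 to 147652771 in mm9). The filamin-binding gene Rflna (-1.93), the platelet glycoprotein gene Gp9 (-1.90), the neuronal adhesion gene Negr1 (-1.57), the T cell factor gene Tcf7 (-1.45) and the cadherin gene Cdh13 (-1.33) fell with adjusted p of 0.0255 to 0.0469, and Fgf14 was at least 1.37-fold lower (0.044). With the slide block, Sfrp2 (adjusted p = 0.0634), Vcam1 (0.0524), Nxpe5 (0.0504), Rflna (0.0651), Tcf7 (0.0553), H2-K1 (0.0599), Ndrg1 (0.0597), C1qc (0.0545), Lpl (0.0509) and Adgre1 (0.0547) no longer passed. Of the 24 genes the rule named that passed, Uox, Olfr533 and Tenm4 passed without every array; the other 21 missed the threshold without X-ray replicate 2, 3 or 4 or without ALA plus X-ray replicate 2, 3 or 4, with adjusted p up to 0.14, and 0 were lost without replicate 1 of either group.

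**Figure D2:**
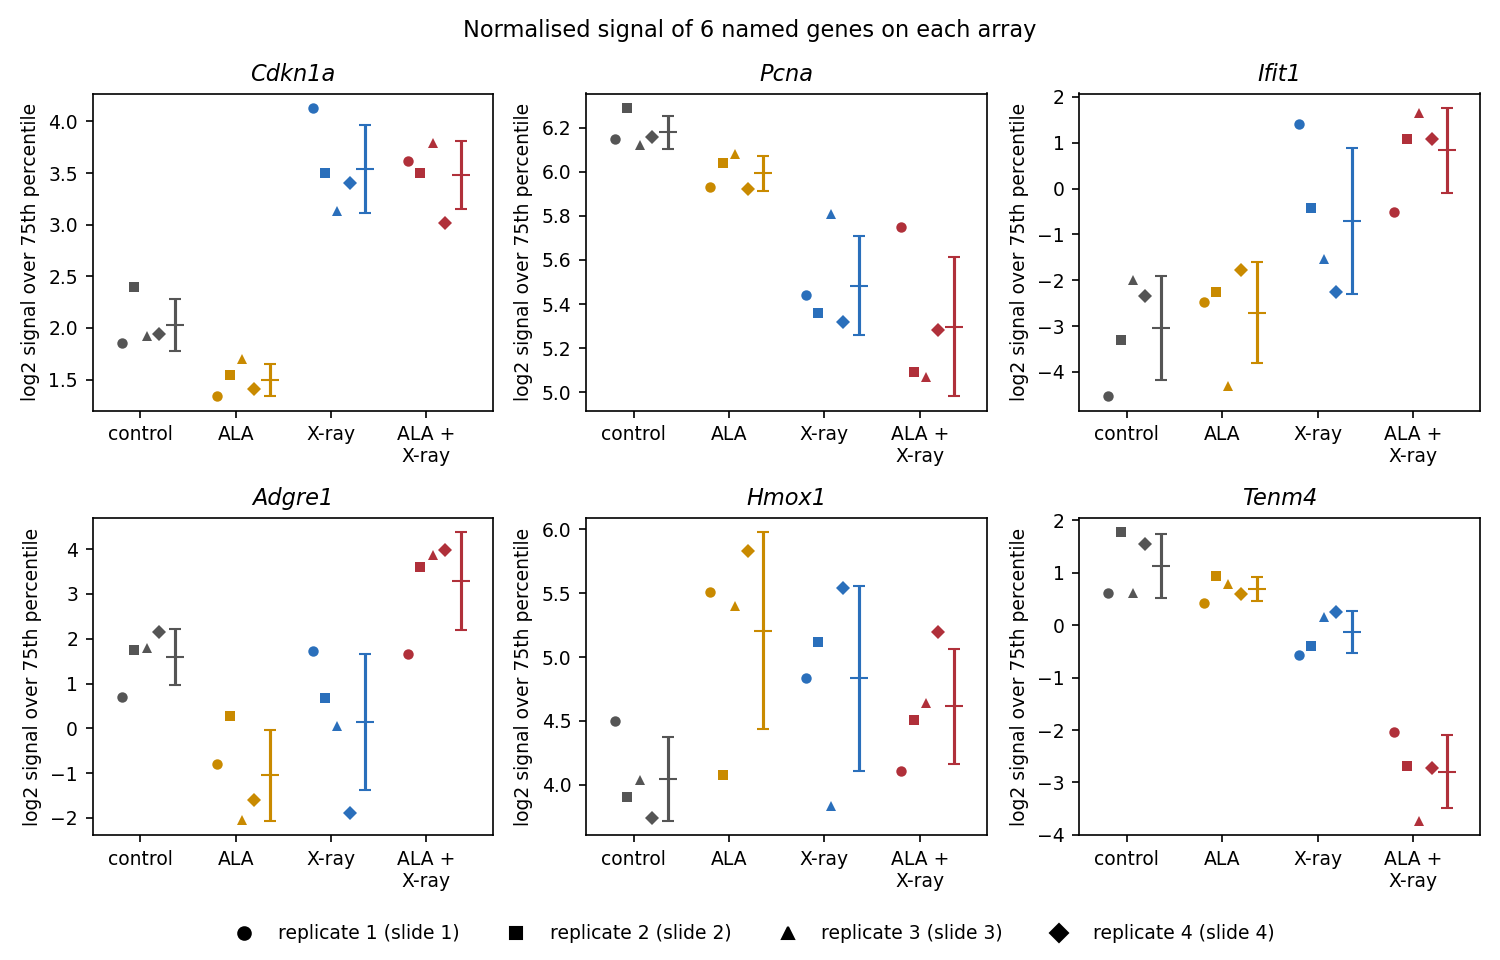
Levels on each array (log2, relative to the array's 75th percentile) of Cdkn1a, Pcna, Ifit1, Adgre1, Hmox1 and Tenm4 in the 4 groups. Bars give the mean and standard deviation of 4 arrays, and symbols the replicate, which is also the slide.

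All 15 macrophage and monocyte markers were above 0 in ALA plus X-ray against X-ray, and 7 rose (14 adjusted over the list alone). Lyz2 rose by 2.27 on the log2 scale (adjusted p = 0.0344), Ms4a7 by 2.96 (0.0377), C1qc by 3.11 (0.043, probe on chromosome 4, 136445766 to 136445825 in mm9) and Adgre1 by 3.14 (SE 0.72, adjusted p = 0.043; chromosome 17, 57622843 to 57622902 in mm9). The list's median was 2.57 (camera, adjusted p = 1.07e-13, adjusted p = 0.51 with an estimated correlation, adjusted p by fry = 0.0555), it kept its call without each array in turn, and within slides 1 to 4 it was -0.29, 2.62, 3.40 and 5.24. The pan-leukocyte gene Ptprc had a log2 fold change of 3.18 and did not pass (adjusted p = 0.0517). All 32 interferon response genes were above 0 with a median of 1.47 (adjusted p = 1.49e-10, adjusted p = 0.51 with an estimated correlation), and 0 members passed by either adjustment; Oasl2 (3.22), Ifi44 (2.75), Ifih1 (1.49) and Gbp3 (2.77) had adjusted p of 0.0887 to 0.116, and Ifit1 (1.54) of 0.255. Within slides the interferon median was -1.75, 1.89, 2.57 and 2.84. All 16 antigen presentation genes were above 0 with a median of 1.46 (adjusted p = 1.7e-06, adjusted p = 0.51 with an estimated correlation), and 1 rose by either adjustment, the MHC class I gene H2-K1, by 2.91 (adjusted p = 0.043). H2-D1 (1.40), H2-Ab1 (3.05) and B2m (0.78) had adjusted p of 0.118 to 0.123, and the list's medians within slides were -1.94, 2.60, 2.33 and 3.09. All 15 inflammatory cytokine and chemokine genes were above 0 with a median of 1.85 (1.54 with dim genes at their bound, adjusted p = 2.71e-08, adjusted p = 0.51 with an estimated correlation). Over all genes 0 passed, and 10 rose adjusted over the list alone, with the monocyte attractant gene Ccl8 at 4.16, Ccl2 at 1.85, Il6 at least 1.29-fold and Ptgs2 at least 1.11-fold higher (adjusted p 0.0517 to 0.0826). Slides 1 to 4 gave medians of -0.86, 2.03, 2.81 and 3.08. T and NK cell markers had a median of 2.16, 10 of 11 above 0 (adjusted p = 0.000242, adjusted p = 0.51 with an estimated correlation), 0 passing over all genes and 3 rising adjusted over the list alone. The granzyme genes Gzma (2.55) and Gzmb (2.25), Klrd1 (2.87) and Nkg7 (3.52) had adjusted p of 0.103 to 0.168, and Cd3e had -0.04 (0.972). The T and NK medians within slides were -2.29, 3.11, 3.33 and 4.90, so slide 1 ran opposite to the others in each of these 5 lists.

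Fibroblast, adipocyte and muscle lists were higher and mitosis and replication lists lower in ALA plus X-ray than in X-ray tumours, while the pericyte and smooth muscle list did not shift (0.09). Slide 1 was opposite for each of the 8 shifted lists here but the endothelial one. All 17 fibroblast and matrix markers were above 0 with a median of 2.04 (1.77 at bound, adjusted p = 4.06e-10, adjusted p = 0.51 with an estimated correlation), 0 passing over all genes and 15 rising adjusted over the list alone. Dpt was at least 5.02-fold and Fap at least 2.69-fold higher, Mmp2 had 1.77 and Fstl1 2.22 (adjusted p 0.0612 to 0.0806). By slide, in order, the median was -0.38, 2.14, 2.73 and 4.00. Adipocyte markers had a median of 2.15 (adjusted p = 0.00357, adjusted p = 0.51 with an estimated correlation), and 1 rose by either adjustment, the lipoprotein lipase gene Lpl, by 2.15 (adjusted p = 0.0447); Fabp4 (0.98), Adipoq (2.35) and Retn (no fold) did not pass. Skeletal muscle markers moved with these lists, at a median of 2.17 (adjusted p = 0.00469, adjusted p = 0.632 with an estimated correlation), with Pvalb (3.47), Ttn (2.17), Myh4 (4.58) and Mylpf (1.93) not passing. Medians on the 4 slides were -4.37, 4.52, 5.18 and 3.56. Neutrophil markers (3 genes) had a median of 2.25 (adjusted p = 0.0244, adjusted p = 0.51 with an estimated correlation; 1 rose adjusted over the list alone), with S100a8 at 2.58, S100a9 at 2.25 and Mmp9 given no fold. Endothelial markers had a median of 0.41 (adjusted p = 0.0244, adjusted p = 0.632 with an estimated correlation), with Kdr (0.81), Flt1 (0.51), Emcn (0.55) and Robo4 (0.54). Of 30 mitosis genes, 29 were below 0 with a median of -0.51 (adjusted p = 1.82e-05, adjusted p = 0.632 with an estimated correlation), with Nusap1 (-0.52), Ube2c (-0.80), Top2a (-0.85) and Kif11 (-0.69). Replication genes had a median of -0.27 (adjusted p = 0.0186, adjusted p = 0.654 with an estimated correlation), with Tk1 (-0.85), E2f1 (-0.68), Mcm7 (-0.66) and Pole (-0.47). Repair genes, of which 0 passed by either adjustment, as in the muscle, endothelial, mitosis and replication lists, had a median of -0.26 (adjusted p = 0.0244, adjusted p = 0.632 with an estimated correlation), with Blm (-0.67), Xrcc1 (-0.47), Xrcc5 (-0.44) and Mre11a (-0.45).

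Hypoxia genes, which shifted up in X-ray against control, were lower in ALA plus X-ray than in X-ray tumours, as were the erythroid markers. Of 24 hypoxia genes, 21 were below 0 and 2 fell by either adjustment: the aldolase gene Aldoc with a log2 fold change of -1.22 (adjusted p = 0.0473) and Ndrg1 of -1.02 (0.0474), with Ddit4 (-0.70) and the hexokinase gene Hk2 (-0.48) at adjusted p of 0.0995 and 0.118. Their median was -0.46 (adjusted p = 0.00469, adjusted p = 0.632 with an estimated correlation). Medians on the 4 slides were -0.80, -0.46, 0.01 and -0.34. The 4 erythroid markers had a median of -2.10 (adjusted p = 0.0244, adjusted p = 0.632 with an estimated correlation), 0 passing over all genes and 3 falling adjusted over the list alone, with Alas2 (-2.97), Hba-a1 (-2.25), Hbb-bt (-1.95) and Slc4a1 (-1.73). Calls of this comparison were lost without X-ray replicate 1 (endothelial 0.28, adjusted p = 0.104), X-ray 2 (neutrophil 2.04, endothelial 0.36, muscle 1.43 and erythroid -1.85, each adjusted p = 0.051), X-ray 3 (replication -0.19 and repair -0.18, each 0.239; neutrophil 1.62, 0.0837) or X-ray 4 (erythroid -1.34, 0.0698). They were also lost without ALA plus X-ray replicate 1 (hypoxia -0.33, adjusted p = 0.221; endothelial 0.39, 0.0546; erythroid -1.84, 0.188), 2 (replication -0.21 and repair -0.23, each 0.0623), 3 (replication -0.07, 0.812; repair -0.14, 0.282; muscle 0.93, 0.143) or 4 (neutrophil 1.45, 0.114; endothelial 0.17, 0.548). The muscle covariate ended the calls of replication (-0.14, adjusted p = 0.126), repair (-0.20, 0.097), neutrophil (1.39, 0.0664) and muscle (0.26, 0.404), and the normexp background those of replication (-0.24, 0.0737), repair (-0.22, 0.109) and endothelial (0.23, 0.0578). The repair call was also lost with no filter (adjusted p = 0.0862), a filter on all 16 arrays (0.0724) and only the arrays compared (0.0538), and the muscle call with that filter (0.0932). Array weights ended the hypoxia and endothelial calls (adjusted p 0.0621 and 0.0824), as did leaving out the first slide (0.505 and 0.117). Mdm2 (0.22), Ccng1 (0.31), Mki67 (-0.61), Ccnb1 (-0.31), Alas1 (0.48), Fech (0.46), Hmox1 (-0.22), Abcg2 (1.15), Tyr (0.22), Il1b (2.15) and Pecam1 (0.59) did not pass, with adjusted p of 0.0661 to 0.762. The other 11 lists did not shift (adjusted p 0.0762 to 0.908), among them p53 targets (0.15, adjusted p = 0.0873), heme synthesis and handling (-0.06, 0.687) and pigmentation (0.07, 0.655).

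**Figure D3:**
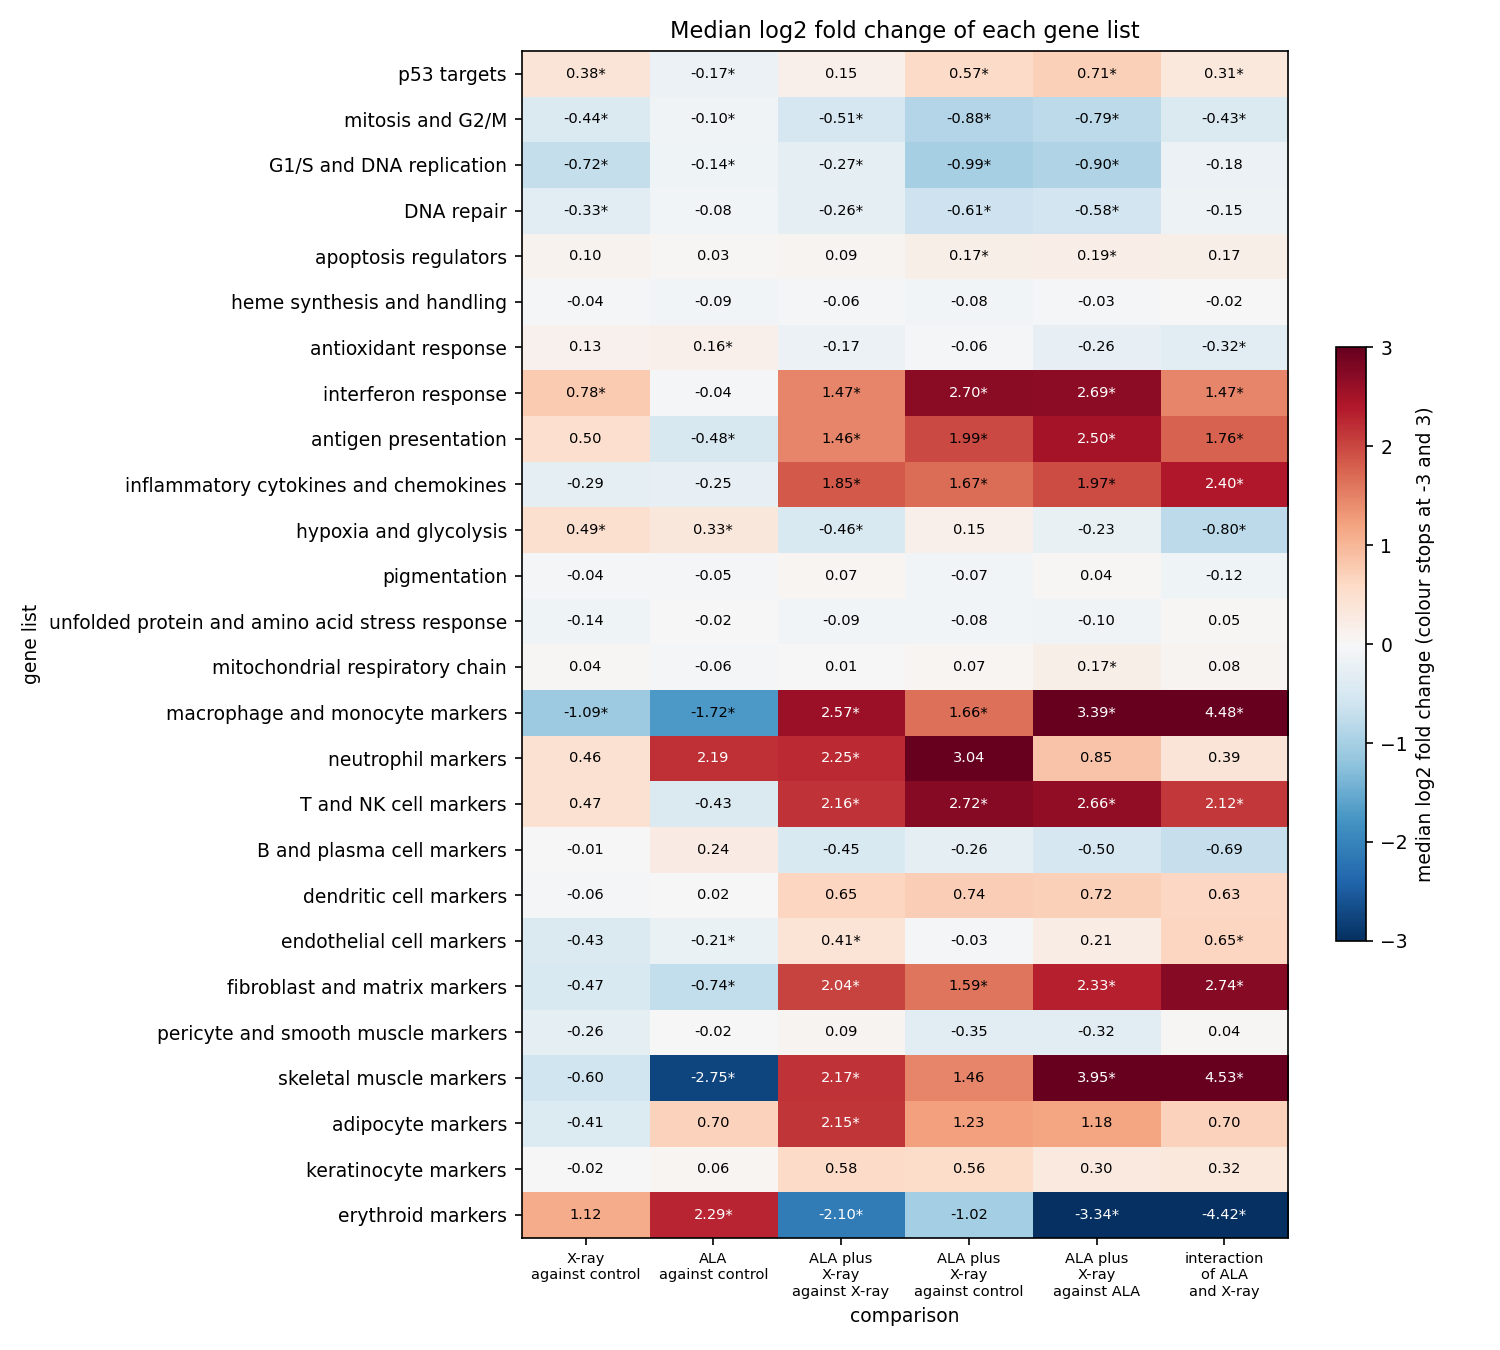
Median log2 fold change of each gene list and marker set in each comparison, with an asterisk where the camera adjusted p was under 0.05. No call had an adjusted p under 0.05 with an estimated correlation.

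Against untreated controls, the combined treatment lowered proliferation genes across the cell cycle and raised interferon, antigen presentation and cytotoxic cell genes. Ifit1, the MHC class I gene H2-K1 and the chemokine gene Ccl5 rose together with the granzyme genes Gzma and Gzmb. The tyrosinase gene Tyr had a log2 fold change of -0.05 (SE 0.20, adjusted p = 0.885). In limma 3828 genes changed, 1504 higher and 2324 lower, 1294 at least 2-fold. Of all genes 6137 had an unadjusted p under 0.05, and 3168 had groups that did not overlap, where chance gives 2.86%. The slide block gave 4147 and the first slide left out 4872. Leaving out 1 array gave 5953 (ALA plus X-ray replicate 1), 2194 (ALA plus X-ray 2), 2191 (ALA plus X-ray 3), 2239 (control 1), 1955 (control 2), 2538 (control 4) or, within 1.5 times of the count, 2626 (ALA plus X-ray 4) or 3493 (control 3). Scaled to the median of each array, 2135 genes passed, 972 higher and 1163 lower.

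The largest rises in ALA plus X-ray against control were Il1rl1, which encodes the interleukin 33 receptor, at 5.64 on the log2 scale (SE 1.28, adjusted p = 0.00959), Wfdc3 at 4.93 (0.00091) and the interferon-inducible GTPase genes Tgtp1 at 4.70 (0.0233), Ifi47 at 4.49 (0.0196) and Gbp2 at 4.34 (0.0239). Pak3 was at least 6.39-fold higher (adjusted p = 0.00091), Gbp6 at least 7.09-fold (0.022) and Bglap at least 12.3-fold (0.00324). Tenm4 fell most, with a log2 fold change of -3.93 (SE 0.34, adjusted p = 0.000167). The squalene synthase gene Fdft1 (-2.24), the retinoic acid hydroxylase gene Cyp26b1 (-2.23), the transcription factor gene Mecom (-2.17), Wnt10a (-2.15), the hair keratin gene Krt85 (-2.11) and Daam2 (-2.08) fell with adjusted p of 0.000559 to 0.0225, and the matrix gene Epyc was at least 2.11-fold lower (0.0055). Over the alternatives Il1rl1 ranged from 2.90 to 6.90, Wnt10a from -2.68 to -0.73, Krt85 from -2.61 to -0.91 and Daam2 from -2.52 to -1.06. Of 65 named genes that passed, 46 passed without every array. Those lost were 16 without control replicate 1, 16 without control 2, 4 without control 3, 5 without control 4, 13 without ALA plus X-ray 2, 15 without ALA plus X-ray 3 and 9 without ALA plus X-ray 4, among them Lyz2, Ctss, Nkg7, Fn1, Mki67, Ccnb1 and Gzmb, with adjusted p up to 0.127.

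Cell cycle genes were lower in ALA plus X-ray than in control tumours almost without exception. Of 30 mitosis and G2/M genes 29 fell (29 adjusted over the list alone), with a median of -0.88 (adjusted p = 4.03e-11, adjusted p = 0.399 with an estimated correlation, 0.00833 by fry). Of 31 replication genes 28 fell (31 adjusted over the list alone), with a median of -0.99 (adjusted p = 1.5e-12, adjusted p = 0.399 with an estimated correlation, 0.00833 by fry). The mitotic regulator gene Foxm1 fell with a log2 fold change of -1.46, Cdk1 of -1.25, Aurkb of -1.04 and Cdc20 of -0.99 (adjusted p 0.00354 to 0.00679), Mki67 of -0.97 (0.0448) and Ccnb1 of -0.87 (0.026). Pcna (-0.89), Ung (-0.91), the clamp loader gene Rfc4 (-1.24) and the methylation maintenance gene Uhrf1 (-1.06) fell with adjusted p of 0.00253 to 0.00495. Of 29 repair genes 22 fell and 1 rose (24 and 1 adjusted over the list alone), with a median of -0.61 (adjusted p = 2.66e-07, adjusted p = 0.399 with an estimated correlation, 0.00833 by fry), led by Xrcc4 (-0.72), Mre11a (-0.81) and the Fanconi gene Fancd2 (-0.87). Of 31 p53 targets 17 rose and 1 fell (18 and 2 adjusted over the list alone), with a median of 0.57 (adjusted p = 4.06e-06, adjusted p = 0.399 with an estimated correlation, 0.0165 by fry). Cdkn1a rose by 1.45 (SE 0.21, adjusted p = 0.00193), Slc19a2 by 0.82, Phlda3 by 1.11, Ak1 by 1.39 (adjusted p up to 0.00705), Mdm2 by 0.71 (0.0154) and Ccng1 by 1.11 (0.0196). Among 19 apoptosis regulators 5 rose and 1 fell (8 and 3 adjusted over the list alone), with a median of 0.17 (adjusted p = 0.0354, adjusted p = 0.399 with an estimated correlation, 0.0603 by fry). The survival genes Bcl2l1 (0.88), Bcl2 (0.64) and Mcl1 (0.55) and the inflammatory caspase gene Casp4 (1.47) rose, with adjusted p of 0.00529 to 0.0151. The apoptosis call was lost with the slide block (adjusted p = 0.0538) and without control replicate 3 (0.18, 0.0518), ALA plus X-ray 2 (0.17, 0.0528) or ALA plus X-ray 3 (0.16, 0.0632). Each of these 5 medians kept its sign within every slide, and slide 1 had the smallest falls (mitosis -0.24, replication -0.32 and repair -0.16). Mki67 missed the threshold with the slide block (adjusted p = 0.0602).

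Interferon, antigen presentation, inflammatory, macrophage and T and NK cell lists were higher in ALA plus X-ray than in control tumours on every slide, but B and plasma cell markers were not (median -0.26). Of 32 interferon response genes 27 rose (32 adjusted over the list alone), with a median of 2.70 (2.65 at bound, adjusted p = 1.19e-14, adjusted p = 0.399 with an estimated correlation, 0.0165 by fry). Ifit1 rose by 3.88 on the log2 scale (SE 0.79, adjusted p = 0.00646, probe on chromosome 19, 34723796 to 34723855 in mm9), Mx2 by 2.70, the RNA sensor gene Ifih1 by 2.22 and Oas1a by 2.30 (adjusted p up to 0.01). Of 16 antigen presentation genes 7 rose (13 adjusted over the list alone), with a median of 1.99 (adjusted p = 1.05e-06, adjusted p = 0.399 with an estimated correlation, 0.0465 by fry), among them H2-K1 (2.63), H2-DMb1 (1.75), the immunoproteasome gene Psmb8 (2.64) and B2m (1.02). Of 15 inflammatory genes 4 rose (8 adjusted over the list alone), with a median of 1.67 (adjusted p = 1.96e-05, adjusted p = 0.399 with an estimated correlation, 0.0465 by fry): the osteopontin gene Spp1 (1.5), Ccl3 (2.93), Ccl4 (2.30) and Ccl8 (3.82). Of 15 macrophage markers 6 rose (6 adjusted over the list alone), with a median of 1.66 (adjusted p = 1.96e-05, adjusted p = 0.428 with an estimated correlation, 0.0709 by fry), including Cd68 (1.29), C1qb (1.83), Ctss (2.20) and Lyz2 (1.39). Of 11 T and NK cell markers 5 rose (8 adjusted over the list alone), with a median of 2.72 (1.48 at bound, adjusted p = 0.000179, adjusted p = 0.399 with an estimated correlation, 0.0465 by fry). Ccl5 rose by 3.17 and Nkg7 by 3.53 (adjusted p 0.00518 and 0.0474), and Gzma was at least 2.16-fold and Gzmb at least 3.79-fold higher (0.0186 and 0.0338). Of 17 fibroblast and matrix markers 4 rose (10 adjusted over the list alone), with a median of 1.59 (adjusted p = 7.12e-06, adjusted p = 0.399 with an estimated correlation, 0.0465 by fry): the matrix genes Sparc (1.57), Mmp2 (2.12), Col5a1 (1.53) and Fn1 (1.76). The lowest medians within a slide were 2.21 for interferon, 1.64 for antigen presentation, 0.32 for inflammatory genes, 0.98 for macrophages, 1.44 for T and NK cells and 0.73 for fibroblasts. With the slide block Gzmb (adjusted p = 0.051), Nkg7 (0.0643), Col5a1 (0.0609) and Fn1 (0.0652) missed the threshold.

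**Figure D4:**
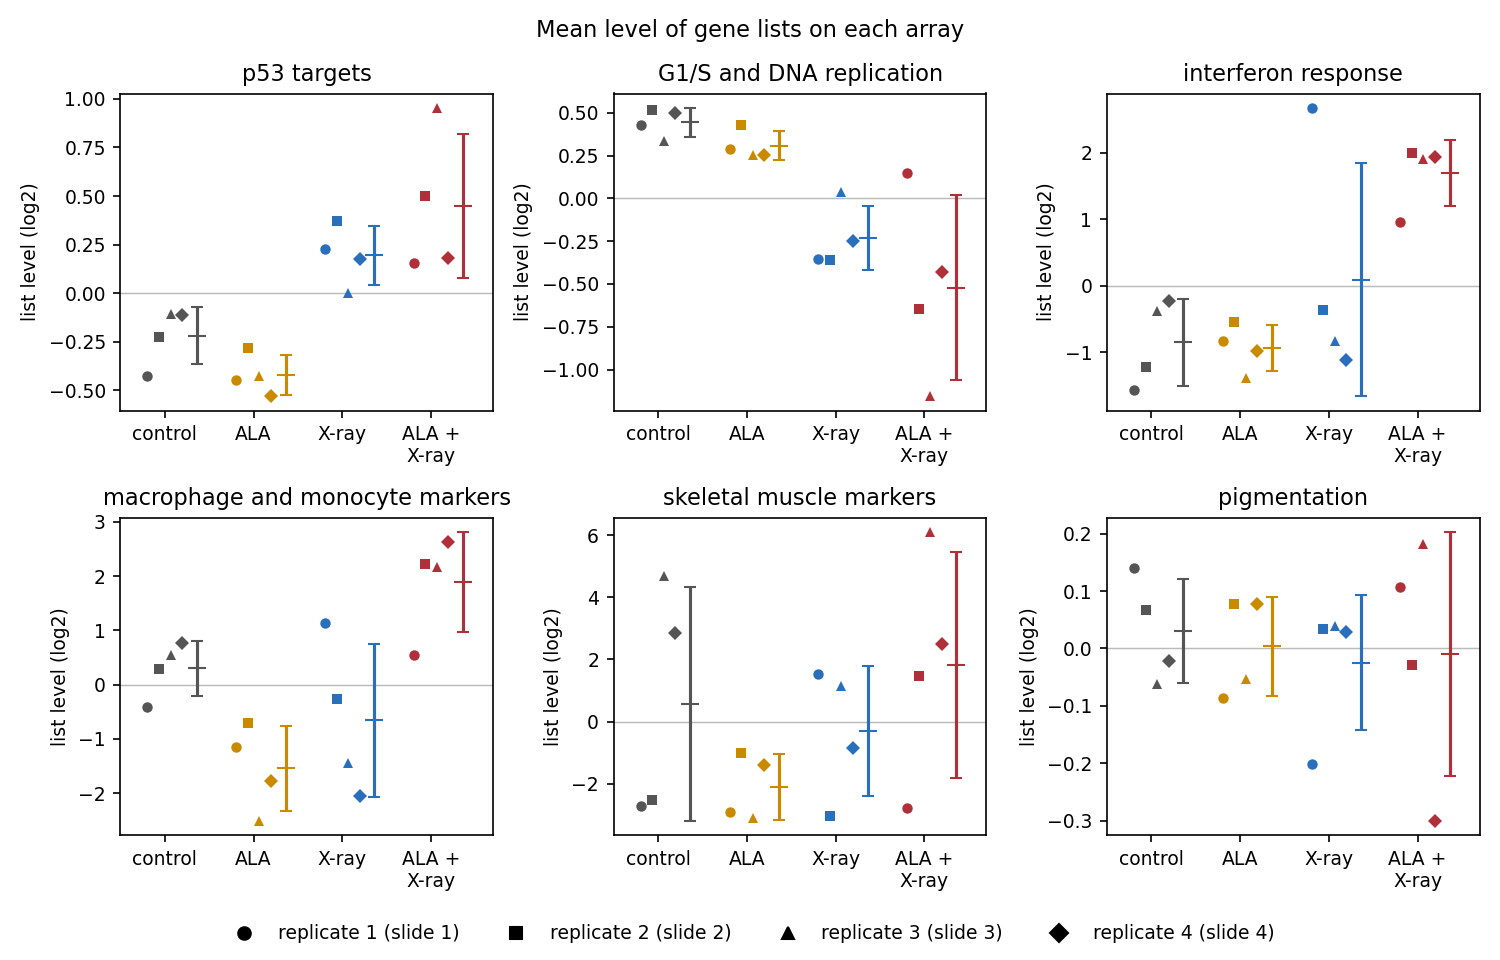
Mean level (log2) of p53 target, replication, interferon, macrophage, skeletal muscle and pigmentation lists on each of the 16 arrays. Bars give the mean and standard deviation of 4 arrays, and symbols the replicate, which is also the slide.

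Abcg2, whose protein exports porphyrins, rose by 1.02 in ALA plus X-ray against control (SE 0.32, adjusted p = 0.0326). Its other probe (0.90) did not pass, and 7 of 21 alternatives ended the call, with adjusted p up to 0.103: median scaling, no filter, only the arrays compared, and leaving out control replicate 1 (0.99, 0.0736) or 2 (0.78, 0.103) or ALA plus X-ray 3 (0.86, 0.0977) or 4 (0.81, 0.0946). The heme genes Alas1 (0.23), Fech (0.55) and Hmox1 (0.57) did not pass (adjusted p 0.091 to 0.668). Ptprc (1.93), Cd3e (0.78), Adgre1 (1.69), Il1b (1.67) and Pecam1 (0.08) had adjusted p of 0.0896 to 0.862. The other 15 lists did not shift (adjusted p 0.0974 to 0.952): heme synthesis and handling had a median of -0.08 with 3 genes up and 2 down of 18 (adjusted p = 0.715), pigmentation -0.07 with 1 up and 1 down of 17 (0.815), endothelial markers -0.03 (0.952) and skeletal muscle markers 1.46 (0.148).

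By limma, the difference made by ALA was not the same in irradiated and unirradiated tumours for some genes. The interaction of ALA and X-ray, which tests that difference itself, passed for 189 genes, 138 positive and 51 negative, in limma (157 at least 2-fold; 2938 with an unadjusted p under 0.05). The leukocyte inhibitory receptor gene Lair1 had an interaction of 6.70 on the log2 scale (SE 1.22, adjusted p = 0.0295), Ccl8 of 6.63 (0.0495), Rbp4 of 6.62 (0.0379), the myeloid gene Ly86 of 6.04 (0.0313) and the C-type lectin gene Clec4a3 of 6.02 (0.0295). Negative ones were Gp9 (-2.37, adjusted p = 0.0295), Tenm4 (-2.21, 0.0439) and Cnn2 (-2.04, 0.0422). Olfr533, well above background on the X-ray arrays alone, and the RNA-binding gene Cpeb4, on no control or ALA plus X-ray array, were negative too (adjusted p 0.0308 each), with no size given. Over the alternatives Lair1 ranged from 2.72 to 8.42, Rbp4 from 2.65 to 8.24 and Clec4a3 from 2.48 to 7.82. With the slide block 8 genes passed, Olfr533 alone among these 10. With the muscle covariate 4 passed, 0 of these 10 among them, with no filter on dim probes 40, and scaled to the median of each array 273, 241 positive and 32 negative. Without 1 array the count was 1065 (ALA plus X-ray replicate 1), 762 (X-ray 1), 400 (ALA 2) or 134 (control 1), and 1 to 39 without any other array; without the first slide it was 1339. Of the 10 genes, lost were 3 without control 1, 9 without ALA 1, all 10 without each of control 2, 3 and 4, ALA 3 and 4, X-ray 2, 3 and 4 and ALA plus X-ray 2, 3 and 4, with adjusted p up to 0.11.

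The macrophage list had the interaction of smallest p, a median of 4.48 with 10 of 15 genes rising (14 adjusted over the list alone; camera, adjusted p = 5.58e-19, adjusted p = 0.411 with an estimated correlation, 0.0127 by fry). By slide, in order, the median was 0.79, 3.33, 7.33 and 8.21. Erythroid markers had a median of -4.42 (adjusted p = 0.000835, adjusted p = 0.541 with an estimated correlation; 4 fell adjusted over the list alone). On slide 1 the sign was opposite for 8 lists. These were interferon response (median 1.47, slide 1 -2.30; adjusted p = 3.16e-07, adjusted p = 0.556 with an estimated correlation) and antigen presentation (1.76, -1.99; adjusted p = 1.07e-06, adjusted p = 0.556 with an estimated correlation). So were inflammatory genes (2.40, -1.20; adjusted p = 3.16e-07, adjusted p = 0.541 with an estimated correlation; 1 rose, 8 adjusted over the list alone) and T and NK cells (2.12, -2.24; adjusted p = 0.00135, adjusted p = 0.556 with an estimated correlation). Stromal lists of this kind were fibroblasts (2.74, -1.82; adjusted p = 1.37e-09, adjusted p = 0.541 with an estimated correlation; 14 rose adjusted over the list alone) and skeletal muscle (4.53, -4.21; adjusted p = 1.23e-05, adjusted p = 0.556 with an estimated correlation). Opposite too were mitosis (-0.43, 0.55; adjusted p = 0.0418, adjusted p = 0.832 with an estimated correlation; 0.0822 with the slide block) and the antioxidant response (-0.32, 0.20; adjusted p = 0.0041, adjusted p = 0.556 with an estimated correlation). Hypoxia genes (-0.80; adjusted p = 7.87e-06, adjusted p = 0.556 with an estimated correlation; 1 fell, 9 adjusted over the list alone) were opposite on slide 2 at 0.12. Endothelial markers (0.65; adjusted p = 0.0047, adjusted p = 0.556 with an estimated correlation) were so on slide 2 at -0.03 and p53 targets (0.31; adjusted p = 0.0047, adjusted p = 0.565 with an estimated correlation) on slide 4 at -0.06. The p53 call was lost without ALA plus X-ray replicate 3 (0.13, adjusted p = 0.0647) and the endothelial call without ALA plus X-ray 4 (0.39, 0.0731). The mitosis call was lost without control 1 (-0.40, adjusted p = 0.0938), control 3 (-0.37, 0.0694), ALA 1 (-0.40, 0.0676), ALA 2 (-0.38, 0.0786), ALA 3 (-0.44, 0.0599), X-ray 3 (-0.32, 0.387), ALA plus X-ray 2 (-0.35, 0.103) or ALA plus X-ray 3 (-0.12, 0.593), with no filter (0.0552) and with a filter on all 16 arrays (0.0543). The muscle covariate ended the mitosis (-0.08, adjusted p = 0.754), p53 (0.28, 0.0864) and muscle calls (0.03, 0.706), the last by its construction. The other 13 lists did not shift (adjusted p 0.0559 to 0.796).

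X-ray in ALA-treated tumours, measured by ALA plus X-ray against ALA, lowered cell cycle genes and raised p53, interferon and macrophage genes. This comparison shares no array with X-ray against control. In limma 3713 genes changed, 1649 higher and 2064 lower, 1382 at least 2-fold; 6100 had an unadjusted p under 0.05, and 3195 had groups that did not overlap, where chance gives 2.86%. The slide block gave 4102, the median of each array 1896, 1360 higher and 536 lower, and the muscle covariate 673. Of 31 p53 targets 17 rose and 1 fell (20 and 3 adjusted over the list alone; median 0.71, adjusted p = 4.39e-09, adjusted p = 0.376 with an estimated correlation). Mitosis (24 of 30; 29 adjusted over the list alone; -0.79, adjusted p = 1.01e-08), replication (23 of 31; 28; -0.90, adjusted p = 1.72e-09) and repair genes (17 of 29; 20; -0.58, adjusted p = 3.93e-06) fell, each with adjusted p = 0.416 with an estimated correlation. Interferon (28 of 32; 30 adjusted over the list alone; median 2.69, 2.60 at bound, adjusted p = 1.17e-15), antigen presentation (13 of 16; 16; 2.50, 2.41 at bound, adjusted p = 1.84e-09) and inflammatory genes (9 of 15; 12; 1.97, 1.55 at bound, adjusted p = 1.51e-07) rose, each with adjusted p = 0.376 with an estimated correlation. Macrophage (14 of 15; 15 adjusted over the list alone; 3.39, adjusted p = 3.81e-13) and fibroblast genes (14 of 17; 16; 2.33, 2.11 at bound, adjusted p = 5.68e-09) rose as well, each with adjusted p = 0.376 with an estimated correlation. T and NK cell markers rose (6 of 11; 9 adjusted over the list alone; 2.66, 1.93 at bound, adjusted p = 4.11e-05, adjusted p = 0.416 with an estimated correlation). Of 19 apoptosis regulators 6 rose and 1 fell (6 and 1 adjusted over the list alone; 0.19, adjusted p = 0.017, adjusted p = 0.416 with an estimated correlation). Erythroid markers fell (3 of 4; 3 adjusted over the list alone; -3.34, adjusted p = 0.017, adjusted p = 0.44 with an estimated correlation). Skeletal muscle (3.95, 3.39 at bound, adjusted p = 0.000115, adjusted p = 0.529 with an estimated correlation) and mitochondrial respiratory chain lists (0.17, adjusted p = 0.017, adjusted p = 0.692 with an estimated correlation) shifted up with 0 members passing in limma, over all genes or adjusted over the list alone. Slide 1 was opposite for inflammatory genes (-0.59) and fibroblasts (-0.35), and slides 2 and 4 for the respiratory chain (-0.23 and -0.17). Without 1 array the count was 5818 (ALA plus X-ray replicate 1), 2361 (ALA plus X-ray 2), 2219 (ALA plus X-ray 3), 2432 (ALA 1), 2165 (ALA 4) or, within 1.5 times of the count, 2504 (ALA plus X-ray 4), 2882 (ALA 2) and 2779 (ALA 3). The respiratory chain call was lost without ALA plus X-ray 1 (0.09, adjusted p = 0.187) or 3 (0.14, 0.0718), and the erythroid call without ALA plus X-ray 1 (-3.08, 0.122). Array weights ended both (adjusted p 0.31 and 0.0681), the first slide left out the respiratory chain call (0.325), and a filter on all 16 arrays and the muscle covariate the muscle call (0.0858 and 0.606). The other 12 lists did not shift (adjusted p 0.191 to 0.964).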

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

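The splits of the arrays and the comparisons with random lists matched on level were planned before their results were seen; the tests of a lower melanoma share, of muscle content, of a swap and of a slide effect were chosen after. Among 573 groups of 4 values tested for an array far from its group, 38 held one, 7 of 104 list levels and 31 of 469 gene levels, and chance sets apart about 1 in 20.

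Macrophage and monocyte markers were higher in ALA plus X-ray than in X-ray tumours (median 2.57 on the log2 scale). A lower share of melanoma cells would raise all other markers alike. Fibroblast (2.04), adipocyte (2.15), muscle (2.17) and T and NK cell markers (2.16) did rise about as far, but endothelial markers had an upper quartile of 0.54, below the macrophage lower quartile of 2.29, and pericyte (0.09) and erythroid markers (-2.10) did not rise alike. A lower share was thus argued against as the whole cause. A difference between arrays that depends on intensity was argued against, since the list lay at percentile 100 of 10000 random lists matched on mean level (highest median 0.54), and muscle in the tumour pieces was argued against as the whole cause, since the lower quartile was 2.01 with the muscle level as a covariate. That covariate lowered the median to 2.12, and 0 macrophage genes passed with it. The added ALA treatment stays open beside chance, which the splits below do not exclude, other tissue in the tumour pieces, position on the slide, which follows the group, and the doubt about the replicate 1 arrays.

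Mitosis and replication genes were lower in ALA plus X-ray than in control tumours (61 genes, median -0.93, upper quartile -0.78). A lower share of melanoma cells would lower pigmentation genes about as far, but their median was -0.07 and their lower quartile -0.19. An intensity-dependent difference was argued against as well: the genes lay at percentile 0 of random lists matched on level, whose lowest median was -0.40. Less proliferation in the treated tumours stays open beside position on the slide, and bulk arrays do not show in which cells the genes fell.

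Replicate 1 of X-ray and replicate 1 of ALA plus X-ray each stood apart from their groups and toward the other. X-ray replicate 1 lay at a distance of 0.784 from its own group and 0.663 from the other, and ALA plus X-ray replicate 1 at 0.878 and 0.599. The smaller ratio was 1.18, and leaving out 1 array gave 1.10 to 1.25 and 1.29 to 1.53, so a swap of these 2 arrays is a possible explanation. An effect of slide 1 on all of its arrays stays open. The deviations of the 2 arrays correlated at -0.46, but the arrays were picked for departing toward each other, and with control 1 and ALA 1 they correlated at -0.21 and 0.30 (X-ray 1) and 0.54 and -0.06 (ALA plus X-ray 1). Tenm4 (-0.56 on X-ray replicate 1, -2.03 on ALA plus X-ray replicate 1) and Olfr533 (-1.44 and -5.26) followed the printed labels, but were named for separating the groups and so exclude nothing, and tumours that responded unequally would give the same distances.

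The number of genes called was set against other splits of the same arrays. Chance can be excluded for X-ray against control (519 genes; highest other split 2; 1 of 35 as large). So it can for ALA plus X-ray against control (3828; 3218; 1 of 35) and ALA plus X-ray against ALA (3713; 1960; 1 of 35). These splits take no account of slide. They cannot decide ALA against control (0; 0; 35 of 35), with a count of 0, or the interaction (189; 3133; 3 of 100 draws). Its draws also mixed irradiated with unirradiated arrays, and with slide as a block 8 genes passed. Chance cannot be excluded for ALA plus X-ray against X-ray (318; 2594; 2 of 35). The split with 2594 genes exchanged the replicate 1 arrays, which points to a structure of the samples. For the number of shifted lists chance cannot be excluded in any comparison: X-ray against control (7; 16; 31 of 35), ALA against control (11; 13; 4 of 35) and ALA plus X-ray against X-ray (15; 17; 6 of 35). The same holds for ALA plus X-ray against control (11; 17; 23 of 35), ALA plus X-ray against ALA (14; 16; 12 of 35) and the interaction (13; 17; 32 of 100).

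Levels are log2, with the group's nearest other array in parentheses: genes relative to the array's 75th percentile, lists to their mean over all arrays. On ALA plus X-ray replicate 1 they were far from the group for the interferon list at 0.95 (1.91), Oasl2 at 0.57 (2.21), Ifi44 at -3.87 (-1.20), Mx2 at -1.32 (-0.01), H2-K1 at 4.07 (6.09), Ctss at 5.50 (6.66) and Adgre1 at 1.67 (3.61). They were so too for Il1b at -5.35 (-0.74), Ptgs2 at -5.96 (-2.97) and Olfr533 at -5.26 (-6.34). On X-ray replicate 1 they were the T and NK cell list at 2.55 (-0.80), the pigmentation list at -0.20 (0.03), Oasl2 at 2.45 (-2.23), Mx2 at 0.93 (-1.62), Nkg7 at 0.12 (-5.70), B2m at 6.32 (4.91), Fstl1 at 1.13 (0.18), Kdr at -1.93 (-0.88) and C1qtnf9 at -5.80 (-4.44). On the other X-ray arrays they were Ccng1 at 4.05 (3.51; replicate 2), Cdk1 at 3.08 (2.73) and Ero1a at 3.84 (4.55; both replicate 3) and Stra6l at -4.73 (-5.76; replicate 4). The keratinocyte list stood at 2.53 (-0.26) on ALA plus X-ray replicate 4, the adipocyte list at 3.21 (-0.77) on ALA replicate 2 and Col6a1 at -0.67 (-1.37) on ALA replicate 1. On control replicate 1 they were C1qtnf9 at -1.76 (-2.74), Hbb-bt at 6.76 (5.47) and Hba-a1 at 5.92 (4.67), and on control replicate 2 Vtn at -1.31 (-1.87), H2-DMb1 at 0.55 (0.78), Cdkn1a at 2.40 (1.94) and Pde10a at -5.30 (-3.63). Emcn at 1.73 (2.12) and Gzma at -6.71 (-5.45) stood apart on control replicate 3, and the hypoxia list at -0.75 (-0.17), the T and NK cell list at 0.26 (-0.84) and Stra6l at -2.42 (-3.86) on control replicate 4.

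The effect of ALA differed between irradiated and unirradiated tumours by the interaction term for Lair1 (6.70), Ccl8 (6.63), Rbp4 (6.62), Ly86 (6.04), Clec4a3 (6.02), Olfr533 (-3.60), Gp9 (-2.37), Tenm4 (-2.21), Cnn2 (-2.04) and Cpeb4 (-1.95). The values of Olfr533 and Cpeb4 are fitted from signals below background in several groups and measure no size. It differed by camera for the medians of p53 targets (0.31), mitosis (-0.43), antioxidant response (-0.32), interferon response (1.47), antigen presentation (1.76), inflammatory genes (2.40), hypoxia (-0.80), macrophage (4.48), T and NK cell (2.12), endothelial (0.65), fibroblast (2.74), skeletal muscle (4.53) and erythroid markers (-4.42). With an estimated correlation 0 of these 13 list calls held (adjusted p 0.411 to 0.832), and the mitosis call was lost in 12 of 28 other settings, the slide block among them (0.0822).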

How the results depend on the processing

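Apart from the 3 chosen after seeing the data, the alternatives were planned. Comparisons are named here in the order X-ray against control, ALA against control, ALA plus X-ray against X-ray, ALA plus X-ray against control, ALA plus X-ray against ALA and the interaction, and the counts they started from were 519, 0, 318, 3828, 3713 and 189 genes and 7, 11, 15, 11, 14 and 13 lists.

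The quantile normalization, the authors' table, all probes and the 75th percentile over detected spots kept all gene counts within 1.5 times. A 2-fold minimum left 152, 0, 199, 1294, 1382 and 157 genes by its own construction. Array weights called 2962, 40, 2163, 6445, 6438 and 2021 genes, the normexp background 521 in ALA plus X-ray against X-ray, and the slide block 8 in the interaction. Scaling to the median of each array called 28 in X-ray against control, 2135 in ALA plus X-ray against control and 1896 in ALA plus X-ray against ALA. No filter on dim probes left 3, 11 and 40 genes in X-ray against control, ALA plus X-ray against X-ray and the interaction, and shifted 12 lists in X-ray against control and 18 in ALA plus X-ray against control. Only the arrays compared gave 2, 1, 1603 and 1589 genes in the comparisons from ALA against control to ALA plus X-ray against ALA. The muscle covariate gave 812, 76, 673 and 4 genes in X-ray against control, ALA plus X-ray against X-ray, ALA plus X-ray against ALA and the interaction. Without the first slide there were 4, 2982 and 1339 genes in X-ray against control, ALA plus X-ray against X-ray and the interaction, and 12 lists in X-ray against control. An estimated correlation left 0 lists in each of the 6 comparisons, and fry 0 in the first 3 and 1 in the interaction. Apart from the 2-fold minimum, the cause was not tested.

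Leaving out each array in turn gave 1 to 836, 0 to 1, 3 to 3134, 1955 to 5953, 2165 to 5818 and 1 to 1065 genes, and 6 to 10, 5 to 12, 12 to 15, 10 to 15, 12 to 16 and 12 to 17 lists. Genes called in both X-ray comparisons without a shared array were 151 higher and 120 lower. They became 18 and 0 with median scaling, 1 and 0 with no filter, 2 and 0 without the first slide, 520 and 1109 with array weights, 86 and 53 with the muscle covariate, and 279 and 309 at an unadjusted p under 0.01. The lower ones were 194 with the filter on all 16 arrays and 188 with trend and robust moderation, and without each array in turn the counts were 1 to 240 and 0 to 441; the cause was not tested.

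Of the named genes under all alternatives, 5200 values kept their side of the threshold, 201 newly passed and 800 no longer passed. Of called values 0 changed sign. Of list values, 1493 kept sign and call, 224 lost the call and 1 reversed. This was fibroblast markers in ALA against control, 0.016 with the muscle covariate in place of -0.74. The cause was not tested. Signal over background limits the dim genes: 44.3% to 53.6% of spots were well above background, and a gene below it on every array of a group has a bound or no fold.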

Other observations

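The overlap of the X-ray comparisons and the list values were planned; the overlap of the ALA comparisons and the correlations across genes were chosen after the results were seen. Genes called after irradiation with and without ALA overlapped, in comparisons that share no array, but the overlap depended on single arrays and on scaling. Of 307 genes higher in X-ray against control, 151 were also among the 1649 higher in ALA plus X-ray against ALA (32.9 if independent), and 3 were among the 2064 lower (41.2). Of 212 lower genes, 120 were also among the 2064 lower (28.4) and 5 among the 1649 higher (22.7). The 151 and 120 genes became 18 and 0 with median scaling and 2 and 0 without the first slide. Without 1 array they became 69 and 20 (control replicate 1), 2 and 0 (control 2), 69 and 68 (control 3), 1 and 0 (control 4), 82 and 63 (ALA 1), 114 and 79 (ALA 2), 68 and 49 (ALA 4), 1 and 0 (X-ray 1), 5 and 1 (X-ray 2), 218 and 204 (X-ray 3), 3 and 0 (X-ray 4), 240 and 441 (ALA plus X-ray 1), 92 and 67 (ALA plus X-ray 2) or 136 and 79 (ALA plus X-ray 4). Across all genes the log2 fold changes of the 2 comparisons correlated at 0.08, and genes are not independent replicates.

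Differences with ALA ran mostly in opposite directions in unirradiated and irradiated tumours, although 0 genes passed in ALA against control and chance cannot be excluded for the gene count of ALA plus X-ray against X-ray. The log2 fold changes of ALA against control and ALA plus X-ray against X-ray, which share no array, correlated at -0.46 across genes. At an unadjusted p under 0.01, 140 genes were higher with ALA alone; 0 of them were among the 767 higher in ALA plus X-ray against X-ray (7 if independent) and 13 among the 624 lower (5.7). Of 57 genes lower with ALA alone, 1 was among the 624 lower (2.3) and 34 among the 767 higher (2.8).

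Heme synthesis and handling did not shift in any comparison, with medians of -0.04, -0.09, -0.06, -0.08 and -0.03 in the 5 comparisons of groups and -0.02 in the interaction. In ALA plus X-ray against ALA 3 of its 18 genes rose and 1 fell (3 and 1 adjusted over the list alone). Neutrophil markers (3 genes) had 2.19 in ALA against control (adjusted p = 0.107) and 3.04 in ALA plus X-ray against control (0.0974).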
